A study of Homo sapiens with 6 samples.

How the data were processed

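RNA of 2 human diffuse large B-cell lymphoma lines was measured on 6 Affymetrix HG-U133 Plus 2.0 arrays, 1 per sample, as named by the probe annotation. Per the labels' protocols, cells in medium with 10% serum and polybrene at 8 µg/ml were given lentivirus for 2 days and puromycin at 1 µg/ml for 2 days, with 1 hairpin sequence per arm. RNA was extracted with Trizol and passed over RNeasy columns, per the labels' protocols. Groups and replicate numbers came from the sample titles, which call the KARPAS-422 arrays biological replicates.

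The deposited table holds log2 signals of the authors' MAS5 step, named without a version in the submitters' processing notes. MAS5 summarises each probe set on 1 array and scales each array separately. The log base and the target were not stated. Taking 2 to the power of each value gave a 2% trimmed mean between 499.86 and 499.88 on all 6 arrays, so the values were read as log2 of signals scaled to a common target. No normalization between arrays beyond this scaling was seen. Detection calls and scan dates were not analysed here, so probe sets without signal above background were not marked and no batch could be tested. MAS5 spreads dim signals widely on the log scale: deposited values ranged from -4.57 to 14.82, and a large log2 difference of a dim gene has an uncertain size. The annotation gave 1 gene symbol for 41091 of 54675 probe sets, several for 1801 and none for 11721, and 62 were Affymetrix controls. Gene IDs matched a RefSeq table (GRCh38.p14 names) for 41037 of the single-gene probe sets, and 0 symbols changed.

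Control probe sets and probe sets with several symbols or none were left out of the gene table. A probe set was kept where at least 2 of the 6 arrays lay above the median of all deposited values (6.21). Each gene was represented by its kept probe set with the highest mean, which gave 13036 genes, of which 6559 had more than 1 such probe set. Among genes called in KARPAS-422, 1897 had several kept probe sets and 556 of these had 1 or more of the opposite sign. Among the 175 genes named by the rules below, 13 did: QKI, DLG3, DIXDC1, RBBP4, PHC3, BHLHE41, ERN1, XBP1, PLCG2, AURKB, BCL2, CIITA and CD9. No pseudocount was added, since the values already were log2.

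Tests used limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. KARPAS-422 and the difference between lines were fitted in a model of 4 groups over all 6 arrays. The Pfeiffer groups of 1 array add no residual degrees of freedom, so the spread came from 2 residual degrees of freedom in KARPAS-422 and 5.24 prior ones. The comparison over both lines had a term for the line and 3 residual degrees of freedom. Pfeiffer alone was not tested: differences and counts at 1 log2 unit are given beside the same counts between KARPAS-422 replicates. Each adjusted p for a single gene is limma's.

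There were 25 gene lists: PRC2 subunits, other Polycomb and demethylase genes, germinal centre B cell genes, plasma cell genes, B cell activation and light zone genes, B cell receptor signalling, G2 and M phase, S phase and E2F targets, cyclin-dependent kinase inhibitors, pro-apoptotic, anti-apoptotic and p53 target genes, MHC class II, MHC class I, interferon-stimulated genes, unfolded protein response, MYC targets and ribosome biogenesis, ribosomal proteins, cholesterol synthesis, glycolysis and hypoxia, homeobox and other developmental regulators, cell adhesion and migration, and markers of T and NK, myeloid, and fibroblast and epithelial cells. Of their 723 genes, 551 were measured. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 25 lists, and again with the correlation estimated from the arrays and with fry. In Pfeiffer a list median was set among 10000 random lists of the same size matched on mean signal, which describes those 2 arrays only. The rules for naming genes were these. EZH2, TXNIP and TNFRSF21 are always named. For KARPAS-422 and for both lines, the 12 genes per direction with the largest called difference are named, provided that all shEZH2 arrays lay beyond all shNTC arrays of the line. For Pfeiffer it is the 10 largest per direction, and for the difference between lines the 5 largest called. For each list it is up to 4 called members per direction, or the 2 with the smallest p. Gene models without a proper name and immunoglobulin segments were passed over. The groups, tests, lists, naming rules and most alternatives were set before the data were examined.

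The scripts were tested on simulated data built from the real means and spreads of 13036 genes with 200 changed. For KARPAS-422 they recovered 70% of genes changed by 1 log2 unit and 93% of those changed by 2, and called 23 unchanged genes. Over both lines they recovered 74% and 96% with 21 unchanged genes called, and for the difference between lines 36% and 81% with 10. In each comparison these unchanged genes were a larger share of the calls than the adjusted p threshold allows on average. The gene counts below may therefore hold more false calls than that threshold implies. Pfeiffer, with 1 array per arm, gave no spread of its own, so the simulation could not check the spread assumed for it.

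Alternatives were pseudocounts of 1 and 76 on the linear scale, no filter and a stricter filter, quantile normalization, centring on array medians, the mean of a gene's probe sets, leaving out probe sets whose names end in _x_at or _s_at (which can bind several transcripts), no intensity trend, a threshold of 0.10, a 1.5-fold threshold, a replicate block, KARPAS-422 arrays alone, and each array left out in turn. The pseudocount of 76 is 4 times the 25th percentile of the linear values, since the planned multiple referred to a pseudocount that the log2 values made unnecessary. A pseudocount of 19, cyclic loess normalization and a 2-fold minimum were added after seeing the data. Figures were drawn with matplotlib 3.10.9.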

Results

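Gene expression was measured on 6 Affymetrix arrays in 2 human cell lines of diffuse large B-cell lymphoma, a tumour of mature B cells. The lines were KARPAS-422 and Pfeiffer. Cells of each line were infected with a lentivirus that carried a short hairpin RNA against EZH2 (shEZH2) or a non-targeting hairpin (shNTC), and the labels give 10 days of knockdown. EZH2 is the catalytic subunit of Polycomb repressive complex 2 (PRC2), which methylates histone H3 and keeps its target genes silent. KARPAS-422 had 2 arrays per arm, labelled as biological replicates, and Pfeiffer had 1 array per arm. The labels do not say whether the replicates came from separate infections, so the p-values measure only the spread between these arrays. The comparisons follow the design text, which names knockdown against control in each line. All values are log2 MAS5 signals, and differences are shEZH2 minus shNTC on the log2 scale.

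The arrays had nearly equal overall brightness, with 2% trimmed means between 499.86 and 499.88 on the linear scale. The ACTB control probe sets gave a 3' minus 5' log2 signal of 0.0593 and 0.0830 on the KARPAS-422 shNTC arrays and 0.138 and 0.175 on the shEZH2 arrays, so a small difference in RNA quality between the arms is not excluded. The GAPDH values did not separate the arms, at -0.182 and -0.158 against -0.169 and -0.241. The 2 shNTC arrays of KARPAS-422 correlated at r = 0.978 across the 13036 genes tested, and its 2 shEZH2 arrays at r = 0.982. Across arms within KARPAS-422 the correlation was 0.950 to 0.955. The Pfeiffer arms correlated at r = 0.977, about as closely as KARPAS-422 replicates did. Genes are not independent replicates, so these correlations carry no p-value. The number of arrays limits the precision of every value below.

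EZH2 itself was lower with shEZH2 on every array of both lines. In KARPAS-422 its signal was 11.71 and 11.58 on the shNTC arrays and 10.52 and 10.55 on the shEZH2 arrays, a log2 difference of -1.11 (SE 0.10, n = 2 per arm, adjusted p = 7.73e-04), which left 46.3% of the control level. In Pfeiffer it went from 11.65 to 10.24, a difference of -1.41 that left 37.6% of the control level, with no replicate check. Over both lines the difference was -1.21 (SE 0.11, n = 3 per arm, adjusted p = 0.00764). That call was lost without KARPAS-422 shEZH2 replicate 1 (-1.23, adjusted p = 0.0991), shNTC replicate 2 (-1.28, adjusted p = 0.0541) or shEZH2 replicate 2 (-1.25, adjusted p = 0.12), while the direction held. The gene was read by a single probe set.

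TXNIP, an inhibitor of thioredoxin, rose by 0.69 in KARPAS-422 (SE 0.15, adjusted p = 0.0165) and by 1.10 over both lines (SE 0.25, adjusted p = 0.0444), and read 1.93 higher in Pfeiffer. Its KARPAS-422 call was lost without shEZH2 replicate 1 (0.54, adjusted p = 0.125) or replicate 2 (0.84, adjusted p = 0.0571) and without the intensity trend (adjusted p = 0.113). Its both-line call was lost without any KARPAS-422 array: shNTC replicate 1 (adjusted p = 0.0897) or 2 (adjusted p = 0.155), shEZH2 replicate 1 (adjusted p = 0.195) or 2 (adjusted p = 0.165). It was also lost without the trend (adjusted p = 0.146) or without a filter (adjusted p = 0.0631). The death receptor gene TNFRSF21 passed in KARPAS-422 at 2.15 (SE 0.48, adjusted p = 0.0173) from a dim control signal of 3.59, but the call was fragile. The call was lost without shEZH2 replicate 1 (2.11, adjusted p = 0.103) or replicate 2 (2.20, adjusted p = 0.0944), and with the mean of its probe sets (1.83, adjusted p = 0.0561). On its other probe set alone it did not pass (adjusted p = 0.234): the signal there went from 3.10 to 3.61 on the replicate 1 arrays and from 3.65 to 6.14 on the replicate 2 arrays. With 19 or 76 added to each linear value that other probe set became the brightest, and the difference was 0.84 (adjusted p = 0.236) or 0.39 (adjusted p = 0.269), so these values mix the pseudocount with the change of probe set. Its difference was 0.63 in Pfeiffer and 1.65 over both lines (adjusted p = 0.0667), which did not pass.

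**Figure D1:**
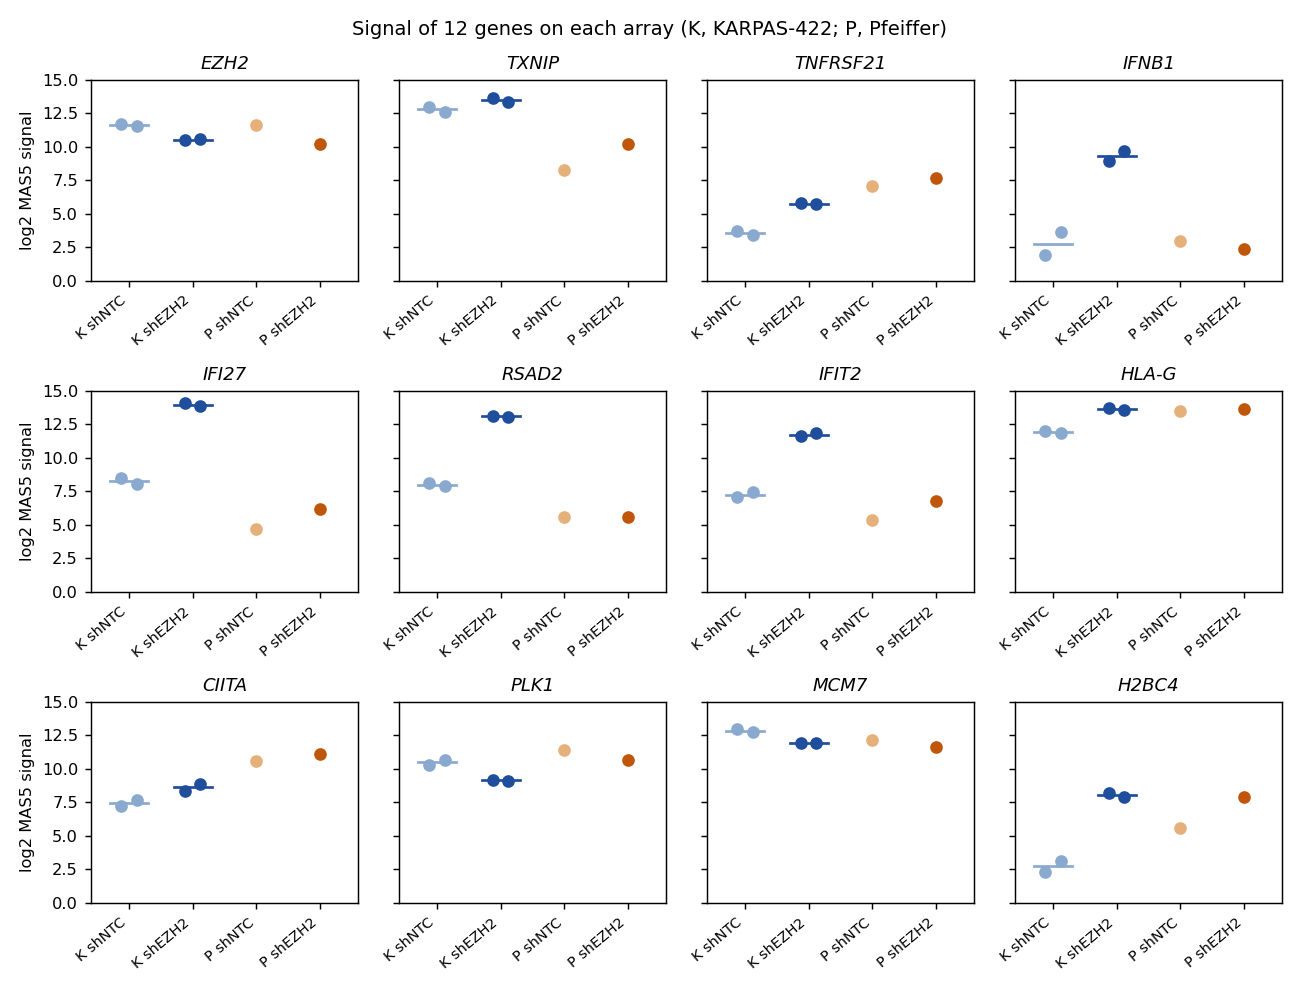
Log2 MAS5 signal (vertical axis) of 12 genes on each of the 6 arrays, 1 point per array, with a bar at the mean of the 2 KARPAS-422 arrays of an arm. EZH2 lies lower with shEZH2 in both lines, while IFNB1 differs by 6.54 in KARPAS-422 and by -0.58 in Pfeiffer.

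In KARPAS-422, all interferon-stimulated genes measured, most MHC class I genes and some MHC class II and B cell receptor signalling genes rose with shEZH2, and most genes of DNA replication and mitosis fell. These list calls used camera with a preset correlation between genes, and none held with an estimated correlation. The adjusted p was then 0.453 for the interferon list, 0.555 for MHC class I, 0.466 for MHC class II and 0.671 for B cell receptor signalling. It was 0.453 for the S phase list and 0.466 for the G2 and M phase list. That estimate rests on 2 residual degrees of freedom. In a single simulated set of arrays with independent genes, a list of 40 genes shifted by 0.5 log2 units also failed that way. Its adjusted p in camera was 0.0506, against 1.16e-76 with the preset correlation. The loss of these calls therefore does not show that a list was unchanged. All 36 interferon-stimulated genes measured rose over all genes tested and when adjusted over the list alone, with a median difference of 2.09. IFI27 rose by 5.68 (SE 0.18, adjusted p = 3.11e-05), the double-stranded RNA sensor gene IFIH1 by 5.57 (SE 0.30), the antiviral gene RSAD2 by 5.10 (SE 0.15) and IFIT2 by 4.49 (SE 0.20). Of 13036 genes tested, 1702 rose and 1603 fell, of which 673 and 118 differed by at least 2-fold.

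MHC class I genes rose as a list in KARPAS-422, with 13 of 16 measured genes higher and 1 lower (14 and 1 adjusted over the list alone) and a median of 0.80. NLRC5, the transactivator of MHC class I genes, rose by 2.04 (SE 0.13), HLA-G by 1.73 (SE 0.08), HLA-F by 1.68 (SE 0.10) and HLA-E by 1.33 (SE 0.08), while the immunoproteasome subunit PSMB8 fell by 0.29 (SE 0.08, adjusted p = 0.0404). The PSMB8 call depended on scaling, since 0 MHC class I genes were lower after quantile or cyclic loess normalization. Of 15 MHC class II genes, 6 rose and 0 fell (7 and 0 adjusted over the list alone). After quantile or cyclic loess normalization 11 were higher, and after median centring 6. As deposited, the 6 higher genes included the class II transactivator CIITA at 1.14 (SE 0.23), HLA-DOA at 0.97 (SE 0.12), HLA-DOB at 0.88 (SE 0.19) and HLA-DPB1 at 0.71 (SE 0.08). Of 26 B cell receptor signalling genes, 10 rose and 1 fell (11 and 1 adjusted over the list alone). CD72, an inhibitory coreceptor of B cells, rose by 3.67 (SE 0.34), FCRL3 by 2.80 (SE 0.13), PRKCB by 2.36 (SE 0.19) and RASGRP3 by 1.89 (SE 0.23). PLCG2 read 0.36 lower on its brightest probe set (adjusted p = 0.0150), but its probe sets ranged from -0.36 to 0.56. The 4 lists passed camera with a preset correlation, with adjusted p of 1.05e-31 for interferon-stimulated genes, 2.74e-08 for MHC class I, 5.30e-04 for MHC class II and 2.17e-04 for B cell receptor signalling. With an estimated correlation none passed, at adjusted p from 0.453 to 0.671. With fry, a rotation test, the interferon (adjusted p = 0.0273), MHC class I (adjusted p = 0.0445) and MHC class II lists (adjusted p = 0.0484) passed and B cell receptor signalling did not (adjusted p = 0.0879).

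Cell cycle genes fell in KARPAS-422. Of 42 S phase and E2F target genes measured, 35 fell and 0 rose (37 and 0 adjusted over the list alone), with a median of -0.55. The replication factor GINS4 fell by 0.97 (SE 0.12), the helicase subunit MCM7 by 0.95 (SE 0.09), the origin recognition gene ORC1 by 0.91 (SE 0.15) and CDC45 by 0.86 (SE 0.10). Of 40 G2 and M phase genes, 28 fell and 0 rose (37 and 0 adjusted over the list alone), with a median of -0.48. The mitotic kinase PLK1 fell by 1.34 (SE 0.15), cyclin A2 (CCNA2) by 1.03 (SE 0.08), CDC20 by 0.85 (SE 0.12) and BIRC5 by 0.79 (SE 0.08). Camera with a preset correlation gave adjusted p of 2.54e-15 for the S phase list and 1.36e-13 for the G2 and M phase list. The S phase list had adjusted p = 0.453 with an estimated correlation, and the G2 and M phase list adjusted p = 0.466 with an estimated correlation. With fry they passed, at adjusted p = 0.0323 and 0.0484.

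Smaller declines were seen in growth and metabolic lists. Of 30 MYC target and ribosome biogenesis genes, 17 fell (20 adjusted over the list alone), among them PA2G4 by 0.82 (SE 0.08), MRTO4 by 0.68 (SE 0.11), the pyrimidine synthesis gene CAD by 0.59 (SE 0.12) and NME1 by 0.55 (SE 0.07). Of 35 ribosomal protein genes, 14 fell (24 adjusted over the list alone), including RPL3 by 0.49, RPS18 by 0.36, RPL8 by 0.33 and RPS6 by 0.32. Of 24 unfolded protein response genes, 9 fell and DNAJB9 rose (11 and 2 adjusted over the list alone), with MANF at -0.79 (SE 0.10), SDF2L1 at -0.71 (SE 0.18) and CRELD2 at -0.67 (SE 0.15). Of 18 cholesterol synthesis genes, 6 fell (7 adjusted over the list alone), including HMGCS1 by 1.14 (SE 0.27), FDPS by 0.83 (SE 0.22), ACAT2 by 0.72 (SE 0.19) and EBP by 0.65 (SE 0.16). Adjusted p with the preset correlation was 2.16e-08 for the MYC list, 4.36e-08 for ribosomal proteins, and 0.00649 for both the unfolded protein response and cholesterol synthesis. With an estimated correlation the MYC list had adjusted p = 0.453, ribosomal proteins adjusted p = 0.701, the unfolded protein response adjusted p = 0.466 and cholesterol synthesis adjusted p = 0.717. The ribosomal protein list had a median of -0.26 as deposited, -0.02 after quantile normalization (adjusted p = 0.909) and 0.07 after cyclic loess normalization (adjusted p = 0.0381), so its direction depended on the scaling. The unfolded protein response list, with a median of -0.47 as deposited, lost its call under the same 2 scalings, at medians of -0.35 and -0.26 (adjusted p = 0.0635 and 0.0659). With fry the MYC list passed (adjusted p = 0.0323), and the ribosomal protein, unfolded protein response and cholesterol lists did not (adjusted p = 0.167, 0.132 and 0.379). Member counts moved with the scaling too: after quantile normalization, median centring and cyclic loess, 11, 26 and 8 MYC target genes fell, 1, 32 and 0 ribosomal protein genes, and 2, 9 and 2 cholesterol genes. In the same order, 7, 12 and 3 unfolded protein response genes fell and 2, 0 and 2 rose. Cholesterol synthesis lost its call without KARPAS-422 shEZH2 replicate 1 (adjusted p = 0.242) and without probe sets that can bind several transcripts (adjusted p = 0.0950).

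The largest increases in KARPAS-422 also included genes outside the lists. The interferon beta gene IFNB1 rose by 6.54 (SE 0.81, adjusted p = 0.00246), the histone genes H2AC6 by 7.6 (SE 0.43) and H2BC4 by 5.33 (SE 0.47), and the nucleic acid sensor gene ZBP1 by 4.93 (SE 0.47). TMEM255A rose by 6.94 (SE 0.87), the protocadherin gene PCDH19 by 5.48 (SE 0.78), HEPACAM2 by 5.45 (SE 0.88), RIN2 by 5.03 (SE 0.35) and the Fc receptor gene FCGR2A by 4.98 (SE 0.77). The largest decreases were SUSD4 at -3.93 (SE 0.92), the cytokine gene IL4 at -3.38 (SE 0.62), KHDRBS3 at -3.15 (SE 0.57), KREMEN2 at -2.83 (SE 0.40), ABCA3 at -2.80 (SE 0.69), CARMIL1 at -2.72 (SE 0.69), DYNC1I1 at -2.64 (SE 0.29) and ADGRV1 at -2.56 (SE 0.59). They were followed by MIR9-3HG at -2.42, GPR157 at -2.29, QKI at -2.27 and RDUR at -2.24. Many of these genes were near the lower end of the signal in 1 arm, where the size of a log2 difference is uncertain. With 19 added to each linear value, H2AC6 differed by 5.98, IFNB1 by 4.61, TMEM255A by 2.59, HEPACAM2 by 3.35, H2BC4 by 3.47 and FCGR2A by 3.13. Each of these 12 decreases except KREMEN2 shrank by more than 1.5-fold, for example SUSD4 to -1.52, IL4 to -1.03 and QKI to -0.08, the last because a different probe set was then the brightest. SUSD4 read 0.51 higher without a filter (adjusted p = 0.715), on another probe set, and lost its call without shNTC replicate 1 (adjusted p = 0.0555), shNTC replicate 2 (adjusted p = 0.0789) or shEZH2 replicate 2 (adjusted p = 0.0615).

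The other 15 lists did not pass camera in KARPAS-422, although some of their members did. Of 31 B cell activation and light zone genes, 7 rose and 1 fell (8 and 1 adjusted over the list alone), with BCL2A1 at 2.04 (SE 0.19), the costimulatory ligand CD86 at 1.65 (SE 0.12), CD40 at 1.14 (SE 0.11), TNFAIP3 at 0.93 (SE 0.20) and lymphotoxin alpha (LTA) at -0.64 (SE 0.14). Of 26 germinal centre B cell genes, 4 rose and 2 fell (3 and 2 adjusted over the list alone), with the transcription factor BACH2 at 3.25 (SE 0.20), the chemokine receptor CXCR4 at 2.36 (SE 0.14), KLHL6 at 1.08, ITPKB at 0.38, SERPINA9 at -0.68 and VPREB3 at -0.46. Of 30 plasma cell genes, 5 rose and 4 fell (6 and 4 adjusted over the list alone), with BHLHE41 at 2.06, JCHAIN at 1.81, ERN1 at 1.15, CHST2 at 1.11, SEC11C at -0.45, PRDX4 at -0.39 and PPIB at -0.29. XBP1 read 0.91 lower on its brightest probe set and 1.5 higher on the other. Of 31 cell adhesion and migration genes, 4 rose and 2 fell (4 and 2 adjusted over the list alone), with PECAM1 at 2.97, ICAM2 at 1.85, LGALS1 at 1.17 and ITGB7 at -0.67, while CD9 was -1.36 on its brightest probe set and 1.21 on another. These counts depended on scaling: after median centring 6 B cell activation genes were higher and 7 lower, 3 and 8 germinal centre genes and 4 and 5 adhesion genes, and after cyclic loess 5 and 0 plasma cell genes.

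Apoptosis and chromatin lists were mixed in KARPAS-422. Of 20 pro-apoptotic genes, 5 rose and 1 fell (5 and 1 adjusted over the list alone), with the TRAIL gene TNFSF10 at 3.55 (SE 0.36), BIK at 2.56 from a dim 2.14 (0.92 with 19 added to each linear value), BNIP3L at 1.01, CASP8 at 0.94 and BID at -0.43. Of 10 anti-apoptotic genes, 4 rose and 1 fell (4 and 1 adjusted over the list alone), with BAG3 at 0.85, BCL2 at 0.80 (-0.31 without _x_at and _s_at probe sets), XIAP at 0.46 and BCL2L12 at -0.44. Of 20 p53 target genes, 3 rose and 2 fell (3 and 3 adjusted over the list alone), with TP53INP1 at 1.36, SESN1 at 0.97, ZMAT3 at 0.59, CCNG1 at -0.48 and TRIAP1 at -0.41. Of 11 PRC2 subunits, 4 fell (2 rose and 4 fell adjusted over the list alone): besides EZH2 these were PHF19 and RBBP4, both at -0.37, and RBBP7 at -0.27, although RBBP4 read 0.11 higher without _x_at and _s_at probe sets. Of 15 other Polycomb and demethylase genes, 3 rose and 1 fell (4 and 3 adjusted over the list alone), with CBX7 at 1.90, PCGF5 at 0.56, PHC3 at 0.45 and CBX6 at -0.40. Of 40 homeobox and other developmental regulator genes, 3 rose and 1 fell (2 and 1 adjusted over the list alone): SOX9 at 1.06, HOXB3 at 0.99, MEIS1 at 0.70 and WT1 at -1.53. Of 26 glycolysis and hypoxia genes, 1 rose and 8 fell (3 and 9 adjusted over the list alone), with KDM3A at 0.54, PFKP at -0.58, ENO1 and ALDOA at -0.39 and PGAM1 at -0.37. In limma, 0 of 5 cyclin-dependent kinase inhibitor genes passed, by either adjustment, and 3 had an unadjusted p under 0.05. CDKN2A was at -0.29 (adjusted p = 0.0525) and CDKN2D at 0.71 (adjusted p = 0.0732). Scaling changed these counts: after median centring 5 pro-apoptotic genes were higher and 6 lower, 3 and 3 anti-apoptotic, 1 and 6 p53 target, 1 and 3 other Polycomb and 2 and 6 developmental regulator genes. PRC2 subunits had 2 lower after quantile normalization, 6 after median centring and 1 after cyclic loess, and glycolysis genes 3, 9 and 1. With fry the anti-apoptotic list passed (adjusted p = 0.0323). The PRC2 list holds the knockdown target itself, so its fry result (adjusted p = 0.0445) is no evidence on the other subunits, and its median was -0.17 as deposited and 0.02 after cyclic loess.

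No marker of other cell types passed as higher in KARPAS-422, which with 2 arrays per arm does not rule out a rise. The lists are a weak check for other cells, since some members were bright in these lines. On the KARPAS-422 shNTC arrays CD3D read 11.4 and 11.2, CD3G 11.7 and 12.1 and CD247 11.8 and 11.9. EPCAM read 13.3 in Pfeiffer shNTC. Of 11 T cell and NK cell markers, 3 fell and 0 rose by either adjustment: CD3D at -0.77 (SE 0.14), CD3G at -0.64 (SE 0.18) and CD247 at -0.44 (SE 0.08). In limma, 0 of 4 myeloid markers and 0 of 7 fibroblast and epithelial markers passed, by either adjustment, with 0 and 1 at an unadjusted p under 0.05. The smallest p among them belonged to ITGAM at -0.76 (adjusted p = 0.226), CSF1R at -0.21 (adjusted p = 0.808), EPCAM at 1.62 (adjusted p = 0.0561) and COL1A2 at 1.95 (adjusted p = 0.127). EPCAM and COL1A2 were dim in KARPAS-422 shNTC, and with 19 added to each linear value they differed by 0.83 and 1.14. The median and the mean had opposite signs for the lists of germinal centre, plasma cell, B cell activation, cyclin-dependent kinase inhibitor, p53 target, cell adhesion, T cell and fibroblast genes, and camera followed the mean for the germinal centre, B cell activation, adhesion and fibroblast lists.

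The 129 genes named for KARPAS-422 include some that were not called, such as CDKN2A and EPCAM. Of the called ones, 65 lost their call without shEZH2 replicate 1, 71 without shEZH2 replicate 2, 31 without shNTC replicate 1, 24 without shNTC replicate 2 and 72 without the intensity trend. Counts in KARPAS-422 rested on both shEZH2 arrays: without replicate 1 of that arm 539 genes were higher and 537 lower, without replicate 2 of that arm 545 and 418, and without the intensity trend in the variance 586 and 134. As deposited, 51.5% of calls were higher and the median gene differed by -0.02, whereas centring each array on its median moved that to -0.19 and left 27.9% of calls higher (1210 higher, 3122 lower).

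Over both lines together, in a model with a term for the line, 20 of 36 interferon-stimulated genes rose. Some antigen presentation and B cell receptor genes also rose, and most cell cycle genes fell. None of these lists passed with an estimated correlation, where adjusted p was 0.249 to 0.424. KARPAS-422 has 2 arrays per arm against 1 in Pfeiffer and so weighs more in this common effect. A call over both lines therefore does not show a change in Pfeiffer. The interferon list had medians of 2.09 in KARPAS-422 and 0.30 in Pfeiffer, and the ribosomal protein list -0.26 and 0.09. The S phase list lay at -0.55 and -0.43. Of all genes tested, 490 rose and 321 fell, with 215 and 11 at 2-fold or more. KARPAS-422 alone had also called 489 of the former higher and all 321 of the latter lower. The largest increases were in H2AC6 at 5.88 (SE 0.94), FCGR2A at 4.34 (SE 0.67), H2BC4 at 4.33 (SE 0.63), IFI27 at 4.29 (SE 0.72), RIN2 at 4.28 (SE 0.48) and the apolipoprotein L gene APOL3 at 3.95 (SE 0.70). IFIT2 rose by 3.48 (SE 0.54), PTPRN2 by 3.38 (SE 0.64), the annexin gene ANXA4 by 3.37 (SE 0.71), the GABA transaminase gene ABAT by 3.29 (SE 0.40), CALD1 by 3.27 (SE 0.71) and the histone gene H2AC8 by 3.26 (SE 0.74). Besides EZH2, the largest decreases were in DDN at -1.71 (SE 0.37), coagulation factor gene F12 at -1.58 (SE 0.29), TEAD4 at -1.49 (SE 0.34), PLK1 at -1.15 (SE 0.16) and TACO1 at -1.14 (SE 0.10). PRKAR2B was at -1.12 (SE 0.22), HMMR-AS1 at -1.11 (SE 0.19), HMGCS1 and DLG3 both at -1.05, DDX51 at -1.02 (SE 0.13) and the fatty acid synthase gene FASN at -0.98 (SE 0.19). With 19 added to each linear value, FCGR2A was at 2.52, APOL3 at 2.03, PTPRN2 at 2.09, ANXA4 at 2.00, CALD1 at 1.79 and H2AC8 at 1.68, and without a filter PTPRN2 was at -0.80 (adjusted p = 0.366).

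By list, 20 of 36 interferon-stimulated genes rose over both lines (34 adjusted over the list alone), including IFI44L by 3.05 (SE 0.46) and OASL by 2.53 (SE 0.44). So did 7 of 16 MHC class I genes (14 adjusted over the list alone), including NLRC5 by 1.5, HLA-F by 1.24, HLA-G by 1.20 and HLA-E by 0.96. Among MHC class II genes 5 of 15 rose (8 adjusted over the list alone), led by HLA-DOB at 1.02 and CIITA at 0.93. Of 26 B cell receptor signalling genes 4 rose (9 adjusted over the list alone): FCRL3 at 2.11, RASGRP3 at 1.5, INPP5D at 0.61 and DAPP1 at 0.59. In the S phase list 28 of 42 fell (36 adjusted over the list alone), with MCM7 at -0.82, ORC1 at -0.73 and CDC45 and GINS4 at -0.72. In the G2 and M phase list 22 of 40 fell (37 adjusted over the list alone), with CCNA2 at -0.88, CDC20 at -0.73 and AURKB at -0.72. Of 30 MYC target genes 4 fell (14 adjusted over the list alone), namely PA2G4 at -0.59, MRTO4 at -0.56, WDR74 at -0.46 and NME1 at -0.42. HMGCS1 alone fell among 18 cholesterol genes (9 adjusted over the list alone) and MANF, at -0.60, among 24 unfolded protein response genes (0 adjusted over the list alone, with 10 at an unadjusted p under 0.05). In limma, 0 of 35 ribosomal protein genes passed by either adjustment, and 1 had an unadjusted p under 0.05.

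These 10 lists passed camera over both lines with the preset correlation, at adjusted p from 1.15e-21 for the S phase list to 0.00574 for the unfolded protein response. With fry only the S phase, G2 and M phase and MHC class II lists passed, each at adjusted p = 0.0182. The fry adjusted p was 0.125 for the interferon list, 0.112 for MHC class I and 0.0633 for both B cell receptor signalling and MYC targets. For the unfolded protein response, cholesterol and ribosomal protein lists it was 0.189, 0.217 and 0.394. With an estimated correlation, camera passed 0 of 25 lists, and 4 had an unadjusted p under 0.05. In a single simulated set of arrays a list of 40 genes shifted by 0.5 log2 units just failed that way too (adjusted p = 0.0506). That draw had independent genes and tested the KARPAS-422 contrast, and its p was below those of the both-line lists. It therefore does not show that low power explains their loss, and the loss does not show that a list was unchanged. The S phase, G2 and M phase, MHC class II and B cell receptor lists each had adjusted p = 0.249 with an estimated correlation. The interferon, MHC class I, MYC and unfolded protein response lists each had adjusted p = 0.424 with an estimated correlation, cholesterol synthesis adjusted p = 0.549 and ribosomal proteins adjusted p = 0.694. Other splits of the 6 arrays gave up to 9 lists past the preset-correlation threshold. The splits with 9 lists set a single KARPAS-422 array against the rest of that line. They keep part of the shEZH2 effect, so they do not give a rate expected without it. The ribosomal protein list over both lines had a median of -0.15 as deposited and 0.08 after cyclic loess normalization, and it lost its call after quantile normalization (adjusted p = 0.921), with the mean of probe sets (adjusted p = 0.0540), without _x_at and _s_at probe sets (adjusted p = 0.178) and without KARPAS-422 shNTC replicate 1 (adjusted p = 0.0514). The unfolded protein response list lost its both-line call after cyclic loess normalization (adjusted p = 0.0707).

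Members of the remaining lists that passed over both lines were few. In the B cell activation list 4 of 31 rose and 0 fell (6 and 1 adjusted over the list alone): BCL2A1 at 1.47, CD86 at 1.17, TNFAIP3 at 0.91 and CD40 at 0.87. In the germinal centre list 1 of 26 rose and 2 fell (3 and 2 adjusted over the list alone): KLHL6 at 0.91, SERPINA9 at -0.73 and VPREB3 at -0.44. In the plasma cell list 1 of 30 rose and 2 fell (2 and 2 adjusted over the list alone): BHLHE41 at 1.55, PRDX4 at -0.42 and SEC11C at -0.40. TNFSF10 at 2.65 was called among 20 pro-apoptotic genes (4 adjusted over the list alone), BCL2A1 among 10 anti-apoptotic genes (2 adjusted over the list alone), and TP53INP1 at 1.40 (SE 0.11) among 20 p53 target genes (3 adjusted over the list alone). HOXB3 at 0.90 was called among 40 developmental regulators (0 adjusted over the list alone), PECAM1 at 2.12 among 31 adhesion genes (0 adjusted over the list alone), PFKP at -0.50 among 26 glycolysis genes (0 adjusted over the list alone) and CD3D at -0.74 among 11 T cell markers (2 adjusted over the list alone). Unadjusted p lay under 0.05 for 7, 8, 10 and 2 genes of the last 4 lists. EZH2 alone passed among 11 PRC2 subunits (2 higher and 1 lower adjusted over the list alone). In limma, 0 genes passed among 15 other Polycomb genes, 5 cyclin-dependent kinase inhibitors, 4 myeloid markers and 7 fibroblast and epithelial markers, with 6, 1, 0 and 0 at an unadjusted p under 0.05 and, adjusted over the list alone, 3 Polycomb genes higher and 3 lower.

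The both-line counts depended on every KARPAS-422 array. The 78 genes named over both lines include some that were not called, such as TNFRSF21. Of the called ones, 63 lost their call without KARPAS-422 shNTC replicate 1, and all 67 did without any other KARPAS-422 array. Without KARPAS-422 shNTC replicate 1, 15 genes were higher and 2 lower (2634 at an unadjusted p under 0.05); without any other KARPAS-422 array limma called 0 (2284 to 2519 at an unadjusted p under 0.05), as it did without the intensity trend (3192). Without a Pfeiffer array the line term absorbs the other one and the fit is that of KARPAS-422 alone (1762 and 1641 without shNTC, 1751 and 1647 without shEZH2), so dependence on a Pfeiffer array could not be tested. Median centring gave 479 higher and 1119 lower, so that 30% of calls were higher instead of 60.4%.

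In Pfeiffer, cell cycle and cholesterol synthesis genes read lower with shEZH2, and MHC class II, B cell activation and interferon-stimulated genes read slightly higher. With 1 array per arm there is no replicate check and no test. Against 10000 random lists matched on mean signal, the median of the S phase list (-0.43) and of the G2 and M phase list (-0.44) lay below all of them, as did cholesterol synthesis (-0.34). The MHC class II list (0.36) and interferon-stimulated genes (0.30) lay above all of them. B cell activation genes (0.33) and MHC class I genes (0.18) were at percentile 99.98, B cell receptor genes (0.21) at 99.95 and ribosomal protein genes (0.09) at 99.92. The ribosomal median in Pfeiffer was -0.00279 after quantile normalization. T cell and NK cell markers (-0.45) were at percentile 0.05 and MYC target genes (-0.16) at 0.07, while unfolded protein response genes (-0.08) were at 9.12. Matched lists keep no correlation between genes, so a shift of genes that vary together from array to array can also lie outside them. The cholesterol genes HMGCS1, FDPS, ACAT2 and EBP all read lower on KARPAS-422 shEZH2 replicate 1 than on replicate 2, with HMGCS1 at 11.48 and 12.46. Such percentiles therefore do not separate an shEZH2 effect from array-to-array spread. Individual interferon-stimulated genes differed in size: 4 of 36 read at least 2-fold higher, including IFI27 at 1.51, IFIT2 at 1.46 and IFI44L at 1.38, and 2 read at least 2-fold lower, including XAF1 at -1.77.

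**Figure D2:**
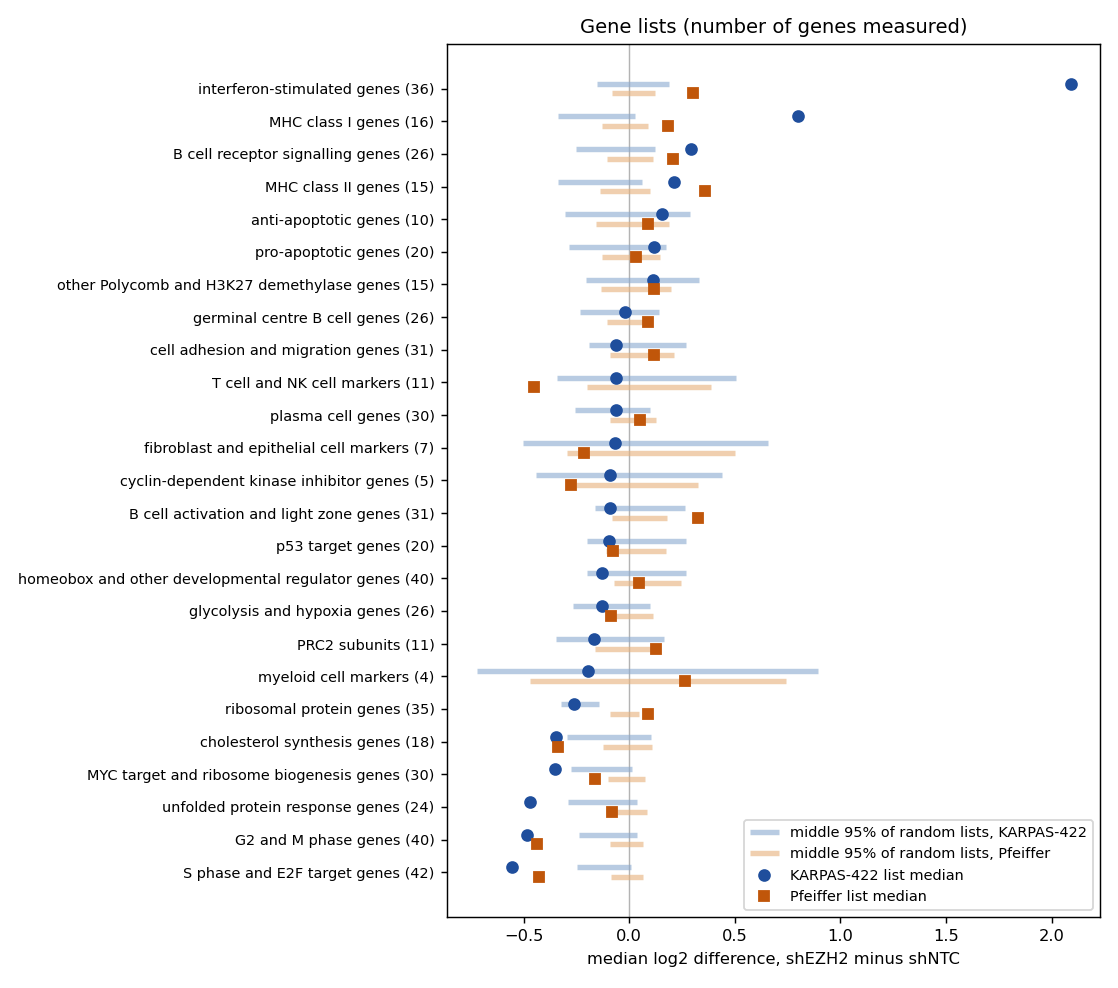
Median log2 difference (horizontal axis, shEZH2 minus shNTC) of each gene list in KARPAS-422 (circles) and Pfeiffer (squares), with bars for the middle 95% of 10000 random lists matched on mean signal. Interferon-stimulated genes lie at 2.09 and 0.30, and the S phase list at -0.55 and -0.43.

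Among single genes in Pfeiffer, the highest differences were in MAP3K5-AS2 at 4.73, the N-acetylglutamate synthase gene NAGS at 4.30, RFPL2 at 4.08, TTN-AS1 at 4.04, PRDM12 at 3.72, GPR18 at 3.63, GALNT7-DT at 3.48, MYADM at 3.36, MIR194-2 at 3.19 and APOL3 at 3.16. The lowest were in CSRNP3 at -5.09, DIXDC1 at -3.79, FAM149A at -3.62, ERICH3 at -3.54, the melanosome gene PMEL at -3.47, SIX2 at -3.38, PCDH19 at -3.07, MYRIP at -3.01, TAF1L at -2.93 and the leukotriene receptor gene LTB4R at -2.83. LTB4R read 0.38 on another probe set. In all, 421 genes were at least 2-fold higher and 193 at least 2-fold lower. Replicate arrays of KARPAS-422 differed by as much in 440 and 341 genes for shNTC and in 308 and 261 genes for shEZH2, so the Pfeiffer counts were of the size that 2 replicate arrays gave. Only 38 of the 421 had a mean signal above that of the median gene tested, and with 19 added to each linear value the counts were 268 and 100. All the single genes named here except GPR18 then shrank by more than 1.5-fold, with MAP3K5-AS2 at 1.25, NAGS at 2.18, CSRNP3 at -0.91, ERICH3 at -0.96, MYRIP at -0.78 and PCDH19 at -0.77, so that sizes and ranks were uncertain.

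The effect of shEZH2 differed between the lines mainly for genes that rose in KARPAS-422. The test of the difference assumed that each Pfeiffer array varies like the KARPAS-422 arrays. That assumption is least safe for genes bright in KARPAS-422 and dim in Pfeiffer. One such gene was CSRNP3, at 10.12 to 11.30 in KARPAS-422 and at 4.15 and -0.95 in Pfeiffer. The test called 222 genes, 163 with a lower effect in Pfeiffer, of which 149 had risen in KARPAS-422, and 59 with a higher effect. The largest negative differences, Pfeiffer minus KARPAS-422, were in PCDH19 at -8.55 (SE 1.34, adjusted p = 0.0282), the pro-apoptotic interferon-stimulated gene XAF1 at -6.05 (adjusted p = 0.00124), CSRNP3 at -5.85 (adjusted p = 0.00393), IFIH1 at -5.24 (adjusted p = 0.00540) and ZBP1 at -5.20 (adjusted p = 0.0282). The largest positive ones were in NUTM1 at 3.52 (adjusted p = 0.0165), ANKRD34A at 3.33 (adjusted p = 0.0167), GPR18 at 3.32 (adjusted p = 0.00564), TTN-AS1 at 3.11 (adjusted p = 0.0280) and LTA at 3.07 (adjusted p = 0.00393). EZH2 (-0.30, adjusted p = 0.417), TXNIP (1.24, adjusted p = 0.0705) and TNFRSF21 (-1.53, adjusted p = 0.388) did not pass.

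By list, 24 of 36 interferon-stimulated genes and 4 of 16 MHC class I genes had a lower effect in Pfeiffer, with median differences of -1.92 and -0.66. Both lists passed camera on the difference with the preset correlation (adjusted p = 6.74e-39 and 7.80e-07), as did ribosomal protein genes (median 0.33, adjusted p = 8.63e-10) and MYC target genes (median 0.24, adjusted p = 0.00312), while all 4 had adjusted p = 0.908 with an estimated correlation. The ribosomal difference rested on the deposited scaling: the list medians in KARPAS-422 and Pfeiffer were -0.0157 and -0.00279 after quantile normalization, and 0.0685 and 0.107 after cyclic loess normalization. Without KARPAS-422 shEZH2 replicate 1 or 2 limma called 0 genes (1914 and 1771 at an unadjusted p under 0.05), without shNTC replicate 1 or 2 it called 389 or 473, and without the intensity trend it called 1 (1828 at an unadjusted p under 0.05). With 19 added to each linear value, PCDH19 was at -4.46 and ANKRD34A at 2.09, while CSRNP3 (-1.66, adjusted p = 0.104) and TTN-AS1 (0.99, adjusted p = 0.248) no longer passed. With the mean of probe sets neither passed (-1.98 and 0.38), with 76 added ANKRD34A did not (1.19, adjusted p = 0.121), and without a filter ZBP1 (adjusted p = 0.0600) and TTN-AS1 (adjusted p = 0.0763) did not.

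Across the 13036 genes, the KARPAS-422 and Pfeiffer differences correlated at Pearson r = 0.193 and Spearman rho = 0.262. The difference between replicate arrays of KARPAS-422 correlated with the Pfeiffer difference at r = 0.0158 for shNTC and r = -0.0185 for shEZH2. Among the 3305 genes called in KARPAS-422, r was 0.395 and rho 0.50. Of the 1702 genes that rose in KARPAS-422, 74.8% read higher in Pfeiffer, against 54.6% of all genes tested, and of the 1603 that fell, 72.4% read lower. The lines share no control arrays, and genes are not independent replicates, so no p-value is given.

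**Figure D3:**
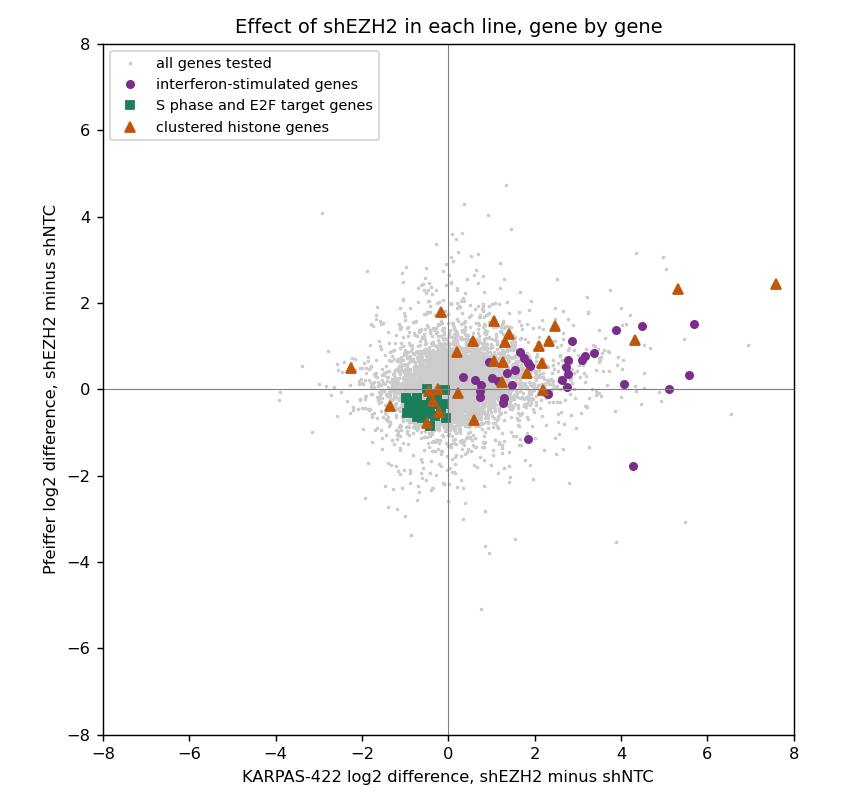
Log2 difference (shEZH2 minus shNTC) of each tested gene in KARPAS-422 (horizontal axis) and Pfeiffer (vertical axis), 1 point per gene, with interferon-stimulated, S phase and clustered histone genes marked. Across all genes r was 0.193, and interferon-stimulated genes spread to 5.68 on the horizontal axis with a Pfeiffer median of 0.30.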

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

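In this part, the tests of array scaling, of the depth of knockdown, of levels in Pfeiffer controls and of the hairpin were chosen after the result was seen, and so was the test of probe sets shared between histone genes. The tests against lists matched on signal and the splits of the arrays were written before their results were seen.

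Interferon-stimulated and MHC class I genes rose more in KARPAS-422 than in Pfeiffer, with median differences between the effects of -1.92 (adjusted p = 6.74e-39) and -0.661 (adjusted p = 7.80e-07) in camera with the preset correlation, and adjusted p = 0.908 with an estimated correlation for both. The tests that follow were run on the interferon list and not on MHC class I genes. Array scaling is argued against, since the median for the interferon list was -2.07 after cyclic loess normalization. EZH2 RNA did not read less reduced in Pfeiffer, where its difference minus that in KARPAS-422 was -0.303 (SE 0.174). That contrast did not pass, as given above, and it rests on 1 Pfeiffer array per arm. EZH2 protein was not measured here, so a weaker knockdown at that level stays open. Levels already high in Pfeiffer controls are also argued against, since Pfeiffer shNTC minus KARPAS-422 shEZH2, taken gene by gene, had a median of -4.93 over the list. A response to the hairpin sequence rather than to the loss of EZH2 cannot be told apart from an EZH2 effect, because the series has 1 EZH2 hairpin. A difference between the lines stays open, and the test of IFNB1 itself did not pass (-7.12, adjusted p = 0.0593).

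Lists of bright genes fell in KARPAS-422, where the brightest of 10 equal bins of genes had a median of -0.24 and a dimmer bin 0.16, so a brightness-dependent shift might account for them. Among 10000 random lists matched on mean signal, the S phase, G2 and M phase and unfolded protein response lists lay at percentile 0, MYC target genes at 0.05 and cholesterol synthesis at 0.43, which argues against the shift as the whole cause. Cyclic loess normalization, which removes such a shift, took the unfolded protein response median from -0.47 to -0.26 (adjusted p = 0.0659), so part of that list's fall may rest on it. Ribosomal protein genes lay at percentile 26.2, where the shift is enough to give their median of -0.26. Matched lists keep no correlation between genes, and a slower growth of shEZH2 cells was not measured here, so no biological explanation was tested.

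The 27 clustered histone genes measured, whose transcripts mostly lack a poly(A) tail, were chosen after H2AC6 and H2BC4 were seen. Of these, 12 rose in KARPAS-422 and 0 fell, and 10 rose over both lines. Reads shared between paralogs could inflate the count, since only 6 of the 19 genes on other probe sets were called higher in KARPAS-422, against 6 of the 8 on _x_at or _s_at probe sets. The 6 on other probe sets argue against shared reads as the whole cause, and part of the count may still rest on them. A change in the share of histone transcripts that carry a poly(A) tail was not tested and stays open.

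The both-line fit called 811 genes, and the highest of the other splits of the 6 arrays into 3 and 3 called 0. It passed 10 lists with the preset correlation, and the highest other split passed 9. In each case 1 of the 10 splits, the real one, gave as many, and 10 splits are too few for a share under 0.05. The other splits also mix the arms, so part of the shEZH2 effect enters their contrast or their residual spread. Neither 9 lists nor 0 genes is therefore a rate expected without an effect.

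Of 175 named genes, 35 had an effect that differed between the lines in limma's test of the difference, with adjusted p up to 0.0465. Among all 13036 genes tested it was 222. The naming rules pick genes partly by this same test and by large effects in 1 line, so the higher share among named genes is no result. Among interferon and sensor genes the differences, Pfeiffer minus KARPAS-422, were -6.05 for XAF1, -5.24 for IFIH1, -5.20 for ZBP1, -5.10 for RSAD2, -4.17 for IFI27, -3.04 for IFIT2, -2.52 for OASL and -2.51 for IFI44L. Among antigen presentation genes they were -1.62 for NLRC5, -1.57 for HLA-G, -1.33 for HLA-F and -1.09 for HLA-E. B cell lists went both ways, with 4 of 8 calls lower in Pfeiffer for receptor signalling, 2 of 4 for germinal centre genes and 1 of 3 for B cell activation. Among B cell and adhesion genes named by rule, the lower effects were -3.57 for CD72, -3.46 for BACH2, -2.55 for PECAM1, -2.40 for CXCR4, -2.39 for LGALS1, -2.14 for PRKCB, -2.08 for ICAM2, -2.07 for FCRL3, -1.44 for CD86 and -1.01 for CHST2. Of these, CXCR4, ICAM2 and CD86 were brighter in Pfeiffer shNTC than on the KARPAS-422 shEZH2 arrays, and the rest were dimmer. CXCR4 read 13.42 against 8.82 and 8.89, ICAM2 12.24 against 9.38 and 8.80, and CD86 12.15 against 11.08 and 10.99. For those genes a high level in Pfeiffer controls stays open as an explanation. Other genes with a lower effect in Pfeiffer were PCDH19 at -8.55, CSRNP3 at -5.85, H2AC6 at -5.15, PMEL at -5.01, DIXDC1 at -4.72, LTB4R at -3.68, MYRIP at -3.35 and ABAT at -2.12. Those with a higher effect in Pfeiffer were NUTM1 at 3.52, ANKRD34A at 3.33, GPR18 at 3.32, TTN-AS1 at 3.11 and LTA at 3.07. With 19 added to each linear value, Pfeiffer differences were -0.91 for CSRNP3, -0.77 for PCDH19, -1.40 for PMEL and -0.78 for MYRIP, but -2.16 for DIXDC1. CSRNP3 (adjusted p = 0.104) and TTN-AS1 (adjusted p = 0.248) then no longer passed limma's test of the difference. LTB4R read 0.38 in Pfeiffer without _x_at and _s_at probe sets. As given above, calls of the difference depended on both KARPAS-422 shEZH2 arrays. The ribosomal protein list (0.334) and the MYC target list (0.236) also had a higher effect in Pfeiffer with the preset correlation, and adjusted p = 0.908 with an estimated correlation. For ribosomal proteins this depended on scaling, as the medians in KARPAS-422 and Pfeiffer were -0.0157 and -0.00279 after quantile normalization.

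Probe sets outside the gene table also carried signal: of 5913 that passed the same filter, 626 rose and 235 fell in KARPAS-422.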

How the results depend on the processing

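Alternatives changed counts more than directions. The pseudocount of 19, cyclic loess normalization and the 2-fold minimum were chosen after seeing the data, and where no cause is given the cause was not tested. In KARPAS-422, the 1702 genes higher became 586 without the intensity trend and 673 with a 2-fold minimum, and the 1603 lower became 3122 after median centring, 901 without _x_at and _s_at probe sets, 134 without the trend and 118 with a 2-fold minimum. Leaving out 1 array at a time gave 539 to 1649 higher and 418 to 1113 lower. Over both lines, the 490 higher became 203 without a filter, 0 without the trend, 1300 at an adjusted p under 0.10 and 215 with a 2-fold minimum, and 0 to 1762 with 1 array left out. The 321 lower became 99 without a filter, 563 with the strict filter, 1119 after median centring, 196 after cyclic loess, 151 without _x_at and _s_at probe sets, 0 without the trend, 1017 at an adjusted p under 0.10 and 11 with a 2-fold minimum, and 0 to 1647 with 1 array left out. The 222 genes that differed between lines became 114 without a filter, 341 with the strict filter and 1 without the trend, and 0 to 473 with 1 array left out. In Pfeiffer, the 421 higher became 95 with a pseudocount of 76, 268 with 19, 1800 without a filter, 145 with the strict filter and 1220 at 1.5-fold, and the 193 lower became 24, 100, 1241, 48 and 603. Dim genes enter without a filter and shrink with a pseudocount, by construction.

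EZH2 over both lines ranged from -1.28 to -1.11 with 1 array left out. The upper ends of this range and of the both-line count ranges come from fits without a Pfeiffer array, which by construction are fits of KARPAS-422 alone. EZH2 has no value without _x_at and _s_at probe sets. The correlation between lines, 0.193, became 0.198 with a pseudocount of 1, 0.284 with 76, 0.238 with 19, 0.0871 without a filter, 0.308 with the strict filter, 0.177 after quantile normalization, 0.173 after cyclic loess, 0.175 without _x_at and _s_at probe sets, and 0.178 to 0.185 with 1 array left out. The share of KARPAS-422 calls with the same sign in Pfeiffer, 73.6%, ranged from 73.2% to 78.9% with 1 array left out. With an estimated correlation camera passed 0 lists higher and 0 lower in KARPAS-422 and over both lines, and fry passed 4 and 4 in KARPAS-422 and 1 and 2 over both lines. With a replicate block in KARPAS-422, 1845 genes were higher and 1878 lower. Directions reversed for CD9 in KARPAS-422 with a pseudocount of 76 (0.21) or 19 (0.53), where another probe set became the brightest, for SUSD4 (0.51) and, over both lines, PTPRN2 (-0.80) without a filter, and after cyclic loess for the ribosomal protein list in KARPAS-422 (0.0685) and over both lines (0.0765) and for RPS6 (0.0217). The mean of probe sets reversed RBBP4 (0.00128), XBP1 (0.30) and PLCG2 (0.19), and leaving out _x_at and _s_at probe sets reversed RBBP4 (0.11), BCL2 (-0.31) and, in Pfeiffer, LTB4R (0.38), since another probe set then stands for the gene.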

Other observations

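Clustered histone genes, which the fixed lists did not hold, had a median difference of 1.06 in KARPAS-422 and 0.63 in Pfeiffer, where 11 of 27 read at least 2-fold higher and 0 as much lower. The KARPAS-422 median stayed between 0.89 and 1.11 under the scalings tried. Besides H2AC6 and H2BC4, H2AC8 rose by 4.32 (SE 0.66), H2BC5 by 2.48 (SE 0.10), the linker histone gene H1-2 by 2.34 (SE 0.15), H4C8 by 2.10 (SE 0.24) and H2BC12 by 0.58 (SE 0.07) in KARPAS-422. In Pfeiffer these read 1.14, 1.48, 1.13, 1.01 and 1.13 higher. Most of the other called genes differed more between the lines. H2AC14 was at 2.19 in KARPAS-422 and -0.02 in Pfeiffer, H2BC9 at 2.16 and 0.62, and H2AC15 at 1.83 and 0.39. H2BC6 was at 1.27 and 0.63, and H2BC12L at 1.31 and 1.11. The 6 histone genes outside the clusters had a median of -0.21 in KARPAS-422, where H2AZ1 fell by 0.32 (SE 0.08) and H2AZ2 by 0.54 (SE 0.09). These genes were chosen after their values were seen.

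Interferon ligands, receptors and sensors were also chosen after the interferon genes were seen, and they differed in direction. In KARPAS-422 the RNA sensor gene RIGI rose by 2.30 (SE 0.12), DHX58 by 3.86 (SE 0.56), the endosomal sensor gene TLR7 by 3.40 (SE 0.62), the interferon lambda receptor gene IFNLR1 by 4.35 (SE 0.59) and EIF2AK2 by 1.26 (SE 0.09), each from limma. The Pfeiffer differences of the same genes were -0.08, -0.50, 1.01, -0.04 and -0.32. The RNA sensor gene TLR3 went the other way, at -0.30 in KARPAS-422 (adjusted p = 0.355) and 2.30 in Pfeiffer, with a difference of 2.59 (adjusted p = 0.0212), and a probe set for the interferon alpha gene IFNA17, of the kind that can bind several transcripts, fell by 1.33 in KARPAS-422 (adjusted p = 0.0216). TLR3 was dim in Pfeiffer, at 2.62 with shNTC and 4.92 with shEZH2, and bright in KARPAS-422, at means of 9.88 and 9.59. The spread in its test came from the bright arrays, so the TLR3 difference is uncertain. The adaptor genes MAVS (0.17, adjusted p = 0.271) and STING1 (-0.05, adjusted p = 0.954) did not pass in KARPAS-422. The median log2 signal of the 36 interferon-stimulated genes was 10.10 in KARPAS-422 shNTC and 12.53 in shEZH2, against 7.89 and 8.05 in Pfeiffer.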
